A study of Oryctolagus cuniculus with 30 samples.

How the data were processed

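RNA was measured in vocal fold mucosa of 15 New Zealand white rabbits, with 3 animals in each of 5 groups and both folds of every animal as separate libraries, 30 in all. Per the labels, libraries were made with the KAPA mRNA HyperPrep kit from 100 ng of RNA with an integrity number above 7 and 15 amplification cycles, and were sequenced as paired reads of 100 bases. The deposited values are raw counts of reads per gene, which the authors made with STAR 2.7.10b. No normalization had been applied to these counts, and the genome build and annotation are not given in the sources used here. Each library has counts without regard to strand and for each strand. Counts on the strand of the second read were used, since they fit the library kit, and unstranded counts served as an alternative. The table has 31346 genes, of which 14615 carry a LOC number and no symbol, and 15808 of the 16731 symbols were found in the RefSeq names, which served for names alone. The 4 entries that name no gene were left out.

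Libraries held 14.2 to 31.9 M gene reads (median 22.7 M). Log2 CPM of the left and right fold of the same animal correlated at a median r of 0.958 (15 pairs), against 0.919 for folds of different animals of a group (60 pairs) and 0.893 across groups (360 pairs). Folds of the same animal nevertheless differed beyond counting error, with a chi-square per degree of freedom of at least 56.2 over genes with at least 20 reads. Since the folds of an animal are not independent, they were summed for the main tests, except for 1 animal in the comparisons with a batch term. A test of right against left folds in 14 animals gave 0 genes by edgeR (1340 of 16800 at an unadjusted p under 0.05); no other tool was run for it. Intervals and lower bounds given for genes with 0 to 3 reads in a group cover counting error alone. Lower bounds set 3 counts over the group in place of 0, and intervals are 95% intervals.

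Tests used R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, genes kept by filterByExpr at a minimum count of 10), and p values were adjusted by Benjamini and Hochberg over the genes tested in each comparison, with 0.05 as the threshold. Libraries came in 2 batches, and 1 injury_only animal has a fold in each. Comparisons of injury_only with control and between materials, and the test over the 3 materials, used 16 units, that animal being divided by batch, with batch as a covariate. Each material was compared with injury_only and with control in a fit of 15 animals without a batch term, and so was the test over the 5 groups, since a batch term there rests on 1 library. CPM levels are TMM-normalized, with SD over 3 animals. The SE of a log2 fold change is its absolute value over the square root of its F statistic, an approximation. List levels are means of log2 CPM with a prior count of 2. Muscle level was compared by an exact permutation test.

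The groups, comparisons, 30 gene lists (561 of 641 genes found), alternatives and the rule for genes named were fixed before the data were examined. Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, with at least 5 members, and again with an estimated correlation and with fry. Camera p values are adjusted over the lists of a comparison. The lists described in the text were chosen after their values were seen. They are skeletal muscle, oxidative phosphorylation, secretory epithelium and glands, ciliated epithelium, T and NK cell, B and plasma cell, antigen presentation, fibroblast, elastic fibre, myofibroblast and TGF-beta response, differentiated squamous epithelium, blood, interferon response, endothelium, cartilage and fibrillar collagens. Genes were named by a rule with 3 parts. The first part takes genes past the threshold with a symbol, a mean of at least 1 CPM and every animal of a group beyond every animal of the other. Of these it names the 10 largest changes in each direction, or 5 for materials against control and for VFLP_man against VFLP_au, and where fewer than 10 genes pass it is filled to 5 by smallest p. The second part takes up to 4 members of each described list by smallest p, and the third a preset group of 10 genes (COL1A1, COL3A1, ACTA2, FN1, ELN, HAS2, TGFB1, MMP1, POSTN and LOX). Results of some genes that the rule takes are not reported here, and no other gene took their place. Lists given only in the closing observations are given without gene names.

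Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, the 30 libraries as separate samples, and limma voom with duplicateCorrelation. Further ones were left or right folds alone, each animal left out, the fit of only the 2 groups, unstranded counts, and batch handled the other way. The muscle level as a covariate (edgeR and limma voom), the control library of lowest depth left out, the injury_only library of batch D left out, and mitochondrial genes left out were added after the data were seen. So was a ranking of genes by how well they part libraries with few and many mitochondrial genes. For that ranking a threshold of 20 for the ratio of the lowest to the highest level was tried first and gave no gene, it was then lowered to 2, and the ranking without a threshold replaced both. The methods were tested on simulated data with the means, dispersions and library sizes of these libraries. There edgeR recovered 19% of genes changed 2-fold and 71% changed 4-fold for injury_only against control (100 genes each), and 29% and 67% for VFLP_man against injury_only. DESeq2 recovered 32% and 87% in the first of these and 52% and 88% in the second. Of the unchanged genes edgeR called 2 in each, where DESeq2 called 54 of 17585 and 60 of 17540. The camera test called a changed list and did not call an unchanged one, in both comparisons. Simulated genes were drawn independently of each other, so this does not test camera on lists whose members vary together.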

Results

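Gene expression was measured by RNA sequencing in vocal fold mucosa from 15 New Zealand white rabbits, with 3 animals in each of 5 groups and the left and right folds of every animal sequenced separately, giving 30 libraries. Control animals were uninjured. The other 4 groups had the superficial mucosa of both folds stripped. Of these, the injury_only group received no injection, and the others received an injection in both folds 7 days later of type I collagen (Col1) or of the hydrogels labelled VFLP (man) and VFLP (au), written here VFLP_man and VFLP_au and made from vocal fold lamina propria according to the series title. Tissue was taken 28 days after treatment in the 4 injured groups, and no time is listed for control. For injury_only, which had no injection, the day from which these 28 days run was not established here. Levels are given as mean CPM (counts scaled to a common library total) ± SD over 3 animals. Fold changes come from the edgeR fit, with an approximate standard error (SE) on the log2 scale derived from the F statistic. Every gene said to rise or fall passed an adjusted p of 0.05.

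The share of reads on skeletal muscle genes differed between groups. It was 6.18 ± 1.65% of gene reads in control (SD, n = 3 animals), 1.78 ± 0.642% in injury_only, 1.24 ± 0.43% in VFLP_au, 0.726 ± 0.334% in Col1 and 0.288 ± 0.213% in VFLP_man. The mean log2 CPM of the muscle list was higher by 3.6 in the 3 control animals than in the 12 injured ones (exact permutation test, two-sided p = 0.0022, over 455 splits). Between 2 groups of 3 animals the smallest two-sided exact p is 0.1. Libraries also fell into 2 batches, C with all 6 control libraries and 5 of injury_only, and D with 1 library of injury_only and all 18 of the injected groups.

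**Figure D1:**
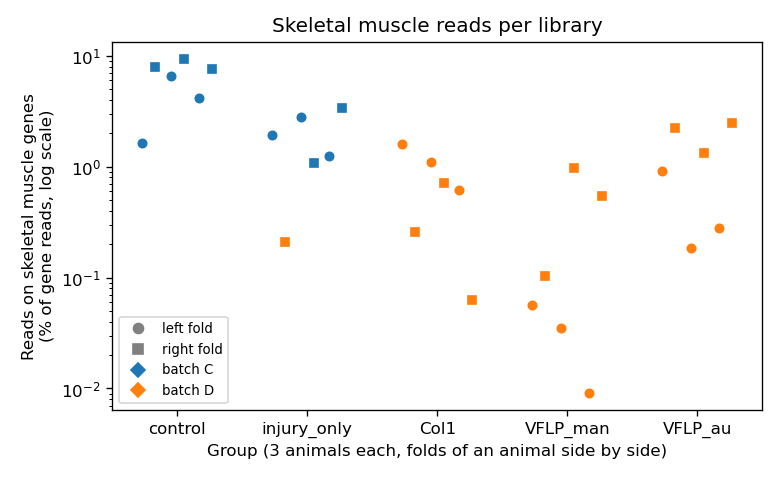
Share of gene reads on the skeletal muscle list (percent, log axis) in each of the 30 libraries, by group, with circles for left folds, squares for right folds and colour for batch. Group means over 3 animals run from 6.18% in control to 0.288% in VFLP_man.

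A preset group of 10 genes of scar and matrix biology was followed through all groups. COL1A1, a chain of type I collagen, averaged 160 ± 33 CPM in control, 127 ± 32.1 in injury_only, 53.2 ± 20.3 in Col1, 66.7 ± 46.6 in VFLP_man and 76.3 ± 47.7 in VFLP_au (n = 3 animals each, here and below). COL3A1, the type III collagen chain, averaged 454 ± 175, 289 ± 80.5, 141 ± 55.8, 191 ± 71 and 241 ± 119 CPM in the same order of groups. Fibronectin, FN1, stood at 452 ± 86, 228 ± 65.9, 72.2 ± 20.8, 103 ± 48.2 and 120 ± 30.2 CPM, and elastin, ELN, at 102 ± 11.4, 67.2 ± 9.35, 37.5 ± 19.9, 48.7 ± 13.1 and 73.2 ± 30.9 CPM. ACTA2, a smooth muscle actin, averaged 64.6 ± 12.1, 114 ± 18.9, 134 ± 120, 21.1 ± 14.6 and 32.2 ± 9.26 CPM. The matricellular gene POSTN averaged 139 ± 26.1, 75.1 ± 18.5, 47.3 ± 17.7, 80.4 ± 22.1 and 62 ± 7.87 CPM. LOX, which cross-links collagen, gave 14.3 ± 4.12, 9.86 ± 0.45, 5.42 ± 2.86, 5.71 ± 0.428 and 9.11 ± 4.37 CPM. HAS2, a hyaluronan synthase, gave 3.9 ± 1.38, 1.62 ± 0.616, 1.02 ± 0.132, 1.04 ± 0.55 and 1.33 ± 0.611 CPM. The collagenase MMP1 was at 0.813 ± 1.02, 2.75 ± 2.13, 2.41 ± 0.844, 6.3 ± 1.46 and 1.15 ± 0.507 CPM, and TGFB1 at 11.1 ± 2.3, 9.28 ± 2.64, 10.6 ± 3.52, 8.85 ± 0.105 and 9.51 ± 2.16 CPM.

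Injured folds with no injection were compared with uninjured folds to ask what stripping left behind at tissue collection. Nuclear genes of oxidative phosphorylation, the mitochondrial route to ATP, fell together: 29 of 30 measured members, also 29 adjusted over the list alone, with a median log2 fold change of -1.45 (camera adjusted p = 1.5e-31, and adjusted p = 0.57 with an estimated correlation). Among them NDUFS7 fell 4.31-fold (SE 0.23), ATP5MC1 3.8-fold (SE 0.23), NDUFS1 3.6-fold (SE 0.22) and NDUFS3 3.18-fold (SE 0.21), each lower in 3 of 3 injured animals than in any control. Skeletal muscle genes, whose share of reads differed between the groups as given above, fell too: 15 of 30, and 23 adjusted over the list alone, with a median log2 fold change of -2.05 (camera adjusted p = 3.3e-08, and adjusted p = 0.58 with an estimated correlation). Examples were the glycogen phosphorylase PYGM (5.35-fold, SE 0.58), the enolase ENO3 (5.19-fold, SE 0.59), the calcium channel CACNA1S (5.09-fold, SE 0.53) and the sarcomere gene TCAP (4.69-fold, SE 0.55).

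Genes of secretory and ciliated epithelium were higher after injury, with a wide spread between folds. The secretory list took 0.03 to 3% of gene reads in the 6 control libraries and 0.27 to 19.26% in the 6 of injury_only, both of these last values being folds of injury_only animal 3. The ciliated list took 0.000889 to 0.0371% in control and 0.00256 to 0.249% in injury_only, the lowest of these again in a fold of animal 3. Libraries of the 2 groups thus overlapped in both lists. Of 20 secretory and gland genes 4 rose, 6 adjusted over the list alone, with a median log2 fold change of 2.22 (camera adjusted p = 1e-05, and adjusted p = 0.58 with an estimated correlation). WFDC2 rose 5-fold (107 ± 52.7 to 533 ± 180 CPM, SE 0.49), AGR2, which folds mucins, 5.91-fold (SE 0.73) and the transcription factor FOXA1 2.71-fold (SE 0.25); BPIFB2 had 406 reads after injury and 0 in control, at least 129-fold higher. Of 26 ciliated cell genes 2 rose, 1 adjusted over the list alone, with a median log2 fold change of 3.74 (camera adjusted p = 3.3e-08, and adjusted p = 0.58 with an estimated correlation). These were MCIDAS, a switch gene of multiciliated cells (13.1-fold, SE 0.82), and CFAP43 (13.2-fold, SE 1.18). CFAP45 was 16.5-fold higher (adjusted p = 0.066) and DRC1 7.88-fold higher (adjusted p = 0.055).

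Lymphocyte genes were also higher in injury_only. Of 13 T and NK cell genes 5 rose, and 5 adjusted over the list alone, with a median log2 fold change of 1.61 (camera adjusted p = 0.0011, and adjusted p = 0.58 with an estimated correlation): CD8A rose 9.53-fold (SE 0.83), CD247 3.3-fold (SE 0.46), IL2RB 3.3-fold (SE 0.39) and the kinase LCK 2.76-fold (SE 0.27). B and plasma cell genes rose in 4 of 14, and 5 adjusted over the list alone, with a median log2 fold change of 1.13 (camera adjusted p = 0.017, and adjusted p = 0.58 with an estimated correlation). POU2AF1 rose 6.19-fold (SE 0.75), PIM2 3.2-fold (SE 0.43) and CD22 3.01-fold (SE 0.52), and TNFRSF13B went from 1 read to 28, a ratio with a 95% counting interval of 4.4 to 1090. Antigen presentation genes rose in 4 of 14, and 5 adjusted over the list alone, with a median log2 fold change of 0.7 (camera adjusted p = 0.015, and adjusted p = 0.58 with an estimated correlation). CIITA, the master regulator of MHC class II, rose 3.46-fold (SE 0.59), CD74 2.58-fold (SE 0.33), TAP2 1.84-fold (SE 0.22) and TAPBP 1.69-fold (SE 0.17).

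Fibroblast and elastic fibre genes were lower. Of 22 fibroblast genes 8 fell, and 15 adjusted over the list alone, with a median log2 fold change of -1.06 (camera adjusted p = 9e-06, and adjusted p = 0.58 with an estimated correlation), among them SCARA5 (3.83-fold, SE 0.43), the proteoglycan DCN (3.37-fold, SE 0.35), PDGFRB (2.89-fold, SE 0.35) and GSN (2.56-fold, SE 0.32). Of 16 elastic fibre genes 5 fell, and 8 adjusted over the list alone, with a median log2 fold change of -0.76 (camera adjusted p = 0.00033, and adjusted p = 0.58 with an estimated correlation), including MFAP5 (4.01-fold, SE 0.38), FBLN2 (2.76-fold, SE 0.33), MFAP2 (2.36-fold, SE 0.39) and LTBP1 (1.74-fold, SE 0.21). With the muscle level of each animal as a covariate in edgeR, 16 of 30 oxidative phosphorylation genes, 4 of 22 fibroblast genes and 2 of 16 elastic fibre genes fell, and 5 of 20 secretory genes, 1 of 13 T and NK cell genes and 1 of 14 antigen presentation genes rose. No ciliated or B and plasma cell gene passed with it, and 1 of 30 skeletal muscle genes, from which the covariate is made, rose. Muscle level did not overlap between injury_only and control, so the covariate can hardly be parted from injury. Of the 10 matrix and scar genes followed throughout, POSTN fell 1.82-fold (SE 0.28, adjusted p = 0.047) and the others did not pass; COL1A1 was 1.25-fold lower (adjusted p = 0.69) and ACTA2 1.75-fold higher (adjusted p = 0.33).

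By size of change, the genes that rose most were CRHBP, which binds corticotropin-releasing hormone (1087 reads against 0 in control, at least 344-fold higher), CALY (398 reads against 2, 95% counting interval 52 to 1570), ANKRD1 (156-fold, SE 1.71) and PPEF2 (72.8-fold, SE 1.98). ROPN1, DEUP1 (a centriole gene of multiciliated cells), OLAH, LGI2, IQCH and ZBED2 rose between 29-fold and 37.2-fold. MYH6, a myosin heavy chain, fell 22.6-fold (SE 1.32) and CA4, a carbonic anhydrase of capillaries, 17-fold (SE 0.71). KCNJ5, OTOA, FAM240B, BTNL9, RNF207, CD36, IL26 and CA9 fell between 11.4-fold and 15.3-fold.

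In all, 3933 of 17815 genes passed in edgeR, 1484 higher and 2449 lower. With the muscle level as a covariate 976 genes passed, including 785 of the 3933. Muscle list means of log2 CPM were 9.052 to 10.17 in control and 6.595 to 8.321 in injury_only. These do not overlap, so that covariate can hardly be parted from injury. Leaving out control animal 2 gave 1733 genes and leaving out injury_only animal 1 gave 1981. Left folds alone gave 0 (3756 at an unadjusted p under 0.05) and right folds alone 4348. Muscle reads were 7.53 to 9.33% in the right folds of control and 0.21 to 3.38% in those of injury_only. In left folds they were 1.62 to 6.63% and 1.25 to 2.8%. The right-fold fit has a batch term, which leaves the right fold of injury_only animal 1, in batch D, without weight.

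**Figure D2:**
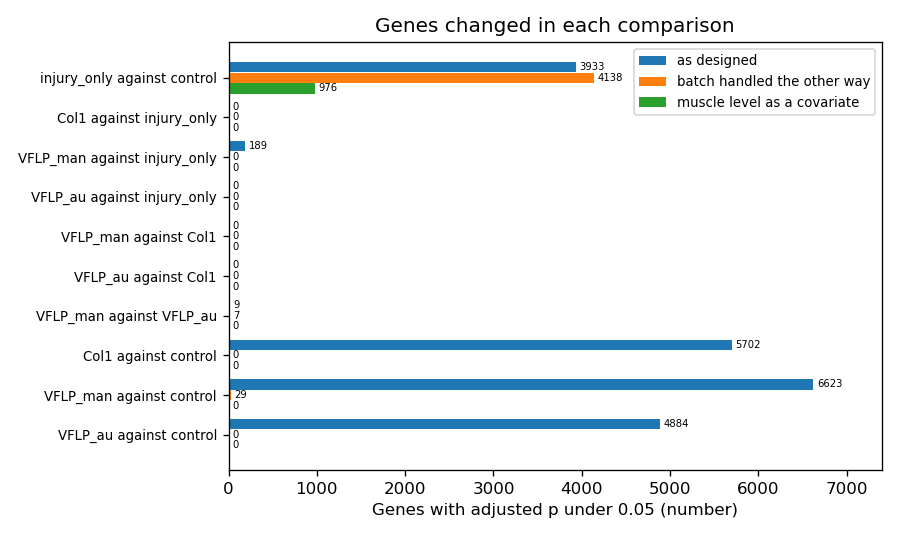
Number of genes with an adjusted p under 0.05 in each comparison (bars, from 0), for the edgeR fit as designed, with batch handled the other way, and with muscle level as a covariate. With the muscle covariate, 976 genes passed for injury_only against control and 0 in each other comparison. Muscle level differed between the groups without overlap in several comparisons, which limits what this covariate can tell.

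Col1 was compared with injury_only to ask how collagen injection altered injured folds. No gene passed. Skeletal muscle genes were lower, with a median log2 fold change of -1.36, 0 of 30 past the test and 0 adjusted over the list alone (camera adjusted p = 1.1e-12, and adjusted p = 0.46 with an estimated correlation); MYH4 was 42.4-fold lower (SE 1.54), PVALB 21-fold, MYBPC2 14.4-fold and MYH3 5.91-fold, at adjusted p from 0.27 to 0.29. PVALB turned to a log2 fold change of 0.45 in left folds alone and 0.8 with the muscle covariate, and MYH3 to 0.61 with a batch term. With a batch term the whole list turned to a median log2 fold change of 1.76, but that term rests on injury_only animal 1, whose batch D fold had 0.21% muscle reads and whose batch C fold had 1.92%. Fibroblast genes had a median log2 fold change of -0.56, with 0 of 22 past the test and 0 adjusted over the list alone (camera adjusted p = 4.1e-05, and adjusted p = 0.46 with an estimated correlation). PI16 was 3.9-fold lower (SE 0.59), TCF21 3.83-fold (SE 0.52), COL1A2 2.35-fold (SE 0.42) and PRRX1 1.94-fold (SE 0.32). Lowest unadjusted p values, none past the test, belonged to AGAP3 (1.86-fold higher), CASTOR1 (2-fold higher), SLC34A3 (2.83-fold higher), CTSK, a collagen-degrading cathepsin (1.99-fold lower), and HMCN2 (3.86-fold lower), all at adjusted p = 0.27. FN1 was 3.16-fold lower (SE 0.35, adjusted p = 0.27). By edgeR 0 of 17770 genes passed, 2530 had an unadjusted p under 0.05, DESeq2 gave 380 and limma voom 3. The groups lie in different batches but for 1 library, and a fit with a batch term gave 0 genes.

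VFLP_man was compared with injury_only to ask the same of that hydrogel. Skeletal muscle genes fell in 7 of 30, and 27 adjusted over the list alone, with a median log2 fold change of -2.77 (camera adjusted p = 9.4e-36, and adjusted p = 0.13 with an estimated correlation): MYH13 fell 113-fold (138 ± 173 to 1.21 ± 0.646 CPM, SE 1.23), MYL3 64.6-fold (SE 1.17), PYGM 11.7-fold (SE 0.65) and ENO3 11-fold (SE 0.66). VFLP_man had the lowest muscle share of the 5 groups. Of 22 fibroblast genes 1 fell, and 8 adjusted over the list alone, with a median log2 fold change of -0.89 (camera adjusted p = 2.8e-08, and adjusted p = 0.22 with an estimated correlation). It was SFRP2, a secreted Wnt modulator (4.63-fold, SE 0.41), while PI16 was 6.9-fold lower (adjusted p = 0.051), DCN 2.34-fold lower (adjusted p = 0.1) and VIM 2.11-fold lower (adjusted p = 0.099). None of the 10 followed matrix genes passed, and ACTA2 came nearest at 5.42-fold lower (SE 0.59, adjusted p = 0.069).

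Of the largest decreases, MYBPHL, MYH13, MYL3, DHRS7C and MSTN (myostatin) are muscle genes. MYBPHL went from 1114 reads to 1, with a 95% counting interval of 273 to 60300 for the ratio. KCNA1 fell 34.3-fold (SE 1), CA14 28-fold (SE 0.76), the cartilage lectin CLEC3A 22.7-fold (SE 0.7), RXRG 21.6-fold (SE 0.94), the lipase LPL 19.9-fold (SE 0.85), and DHRS7C and MSTN 16.8-fold each (SE 0.82 and 0.8). Increases were smaller: MCC rose 2.24-fold (SE 0.22), PLCD3 2.17-fold (SE 0.18), STX7 1.62-fold (SE 0.14) and WASL, an actin regulator, 1.55-fold (SE 0.12), and ATP6V1G1, BNIP3L, AKTIP, GNG5 and MED20 rose between 1.38-fold and 1.5-fold. In all, 189 of 17770 genes passed in edgeR, 13 higher and 176 lower, against 1249 in DESeq2 (336 higher and 913 lower) and 11 in limma voom. Either a batch term or the muscle covariate left 0 genes (989 and 1245 at an unadjusted p under 0.05), and leaving out injury_only animal 2, injury_only animal 3 or VFLP_man animal 1 also gave 0, leaving out VFLP_man animal 3 gave 1 and leaving out VFLP_man animal 2 gave 300. Left folds alone gave 711, right folds alone 0 (912 at an unadjusted p under 0.05) and the 2 groups alone 4.

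VFLP_au against injury_only put the question to the other hydrogel, and no gene passed. Differentiated squamous epithelium, the surface layers of the fold, had a median log2 fold change of 0.9, with 0 of 21 genes past the test and 1 adjusted over the list alone (camera adjusted p = 1.6e-07, and adjusted p = 0.44 with an estimated correlation). CNFN was 2.48-fold higher (SE 0.47), ECM1 2.43-fold (SE 0.45), KRT80 2.16-fold (SE 0.29) and MAL 1.83-fold (SE 0.31), all at adjusted p = 0.35. Myofibroblast and TGF-beta response genes had a median log2 fold change of -0.4, with 0 of 27 past the test and 0 adjusted over the list alone (camera adjusted p = 0.00098, and adjusted p = 0.41 with an estimated correlation). The members of smallest p, none past the test, were CNN1 (4.1-fold lower, SE 0.73), ACTA2 (3.55-fold, SE 0.58), TAGLN (2.96-fold, SE 0.56) and MYL9 (2-fold, SE 0.35). Their adjusted p was 0.35 or 0.36, and which cells of the fold these reads came from was not tested. Smallest unadjusted p values were those of IGFBP2, an insulin-like growth factor binding protein (4.47-fold higher, SE 0.37), ATF4 (1.67-fold higher), NCK2 (1.61-fold higher), ZNF236 (1.55-fold higher) and SNRNP200 (1.4-fold lower), all at adjusted p = 0.35. By edgeR 0 of 17770 genes passed, 2289 had an unadjusted p under 0.05, DESeq2 gave 201 and limma voom 3. These groups too lie in different batches but for 1 library, and a batch term gave 0 genes.

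The 3 materials were compared within batch D. VFLP_man against Col1 showed lower blood genes, all 5 measured members adjusted over the list alone and 0 over all genes, with a median log2 fold change of -3.58 (camera adjusted p = 7.7e-15, and adjusted p = 0.029 with an estimated correlation). HBA was 12.4-fold lower (354 ± 172 to 28.4 ± 10 CPM, adjusted p = 0.082), HBB2 11.9-fold (adjusted p = 0.19) and ALAS2, a haem synthesis enzyme, 11.1-fold (adjusted p = 0.2). Skeletal muscle genes had a median log2 fold change of -1.47, with 0 of 30 past the test and 12 adjusted over the list alone (camera adjusted p = 5.5e-17, and adjusted p = 0.39 with an estimated correlation); MYL3 was 31.5-fold lower, MYH13 21.6-fold, PYGM 4.74-fold and TCAP 4.28-fold. FABP3, a fatty acid binding protein of muscle (12.7-fold lower), FAIM2 (4.73-fold lower), VEPH1 (4.44-fold lower), RELT (4.13-fold lower) and PFKFB1 (9.21-fold lower) had the smallest p, at adjusted p from 0.057 to 0.082. By edgeR 0 of 17815 genes passed, 1832 had an unadjusted p under 0.05, DESeq2 gave 389 and limma voom 5. Left folds alone gave 327.

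VFLP_au against Col1, which shares the Col1 animals with the comparison above, had lower blood genes too, all 5 measured members adjusted over the list alone and 0 over all genes, with a median log2 fold change of -2.57 (camera adjusted p = 5.6e-15, and adjusted p = 0.033 with an estimated correlation). HEMGN was 6.44-fold lower, ALAS2 5.93-fold, HBB2 5.48-fold and HBA 5.04-fold, at adjusted p = 0.99. The blood list mean of log2 CPM was 1.74, 3.05 and 2.35 in the Col1 animals, above all 3 of injury_only (-0.31, 1.72 and 1.28) and overlapping control (1.37, 2.3 and 2.16). Interferon response genes had a median log2 fold change of 1.12, with 0 of 15 past the test and 11 adjusted over the list alone (camera adjusted p = 7.9e-18, and adjusted p = 0.24 with an estimated correlation). Among these antiviral genes OASL was 3.63-fold higher (SE 0.6), IFIT3 3.18-fold (SE 0.54), IFIT2 3.07-fold (SE 0.52) and the RNA sensor IFIH1 1.7-fold (SE 0.24), at adjusted p = 0.99. The list mean of log2 CPM was 4.34, 4.96 and 5.39 in the 3 VFLP_au animals and 4.46, 3.31 and 3.69 in the 3 Col1 animals, so the groups overlapped. FAIM2 (3.45-fold lower), MAGEF1 (3.61-fold lower), CX3CL1 (1.92-fold lower), PSMB10 (1.74-fold higher) and HBA had the smallest p, at adjusted p = 0.99. By edgeR 0 of 17815 genes passed, 829 had an unadjusted p under 0.05, DESeq2 gave 35 and limma voom 11.

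VFLP_man against VFLP_au gave 9 genes, all lower in VFLP_man. FABP3 fell 13.7-fold (SE 0.53), PFKFB1, a glycolytic regulator, 13.6-fold (SE 0.52) and PPM1J 9.69-fold (SE 0.47). RELT fell 6.88-fold (SE 0.32) and the mitochondrial carrier SLC25A34 6.21-fold (SE 0.4). In each of them every VFLP_man animal lay below every VFLP_au animal, which the rule for naming genes requires. Skeletal muscle genes had a median log2 fold change of -2.41, with 0 of 30 past the test and 23 adjusted over the list alone (camera adjusted p = 3.5e-31, and adjusted p = 0.31 with an estimated correlation): MYL3 was 41.7-fold lower, PYGM 7.87-fold, CASQ1 6.81-fold and CACNA1S 5.52-fold, at adjusted p from 0.074 to 0.085. None of the 10 followed matrix genes passed, MMP1 being 5.44-fold higher (SE 0.89, adjusted p = 0.43). DESeq2 gave 387 genes and limma voom 29, of 1489 with an unadjusted p under 0.05 in edgeR. Left folds alone, right folds alone, the 2 groups alone and the muscle covariate each gave 0 in edgeR (1075, 1372, 1401 and 2452 at an unadjusted p under 0.05), and limma voom with that covariate gave 20. Muscle list means of log2 CPM were at most 5.406 in VFLP_man and at least 5.765 in VFLP_au. These do not overlap, so the covariate can hardly be parted from the material. Leaving out VFLP_man animal 1 or VFLP_au animal 1 gave 0 genes, VFLP_man animal 3 gave 1, VFLP_au animal 3 gave 3, VFLP_au animal 2 gave 107 and VFLP_man animal 2 gave 139. The test across all 3 materials gave 0 genes by edgeR (1630 at an unadjusted p under 0.05), 437 by DESeq2 and 42 by limma voom.

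Injected folds were also compared with uninjured ones, to place each material against the starting tissue. Fibroblast genes were lower with each material, in comparisons that share the 3 control animals and set batch D against batch C. Against control, 18 of 22 fell with Col1 (18 adjusted over the list alone, median log2 fold change -1.67, camera adjusted p = 5.8e-10, and adjusted p = 0.43 with an estimated correlation), with PDGFRB 5.48-fold lower (SE 0.36), PDGFRA 5.44-fold (SE 0.36), DCN 5.18-fold (SE 0.36) and PRRX1 3.47-fold (SE 0.32). For VFLP_man 20 of 22 fell (21 adjusted over the list alone, median log2 fold change -1.86, camera adjusted p = 3e-10, and adjusted p = 0.31 with an estimated correlation), with SFRP2 9.14-fold lower (SE 0.42), DCN 8.15-fold (SE 0.37), CLEC3B 6.26-fold (SE 0.39) and PDGFRB 5.96-fold (SE 0.36). For VFLP_au 15 of 22 fell (19 adjusted over the list alone, median log2 fold change -1.33, camera adjusted p = 2.1e-08, and adjusted p = 0.29 with an estimated correlation), with CLEC3B 4.13-fold lower (SE 0.38), PDGFRB 3.95-fold (SE 0.35), DCN 3.64-fold (SE 0.35) and GSN 3.34-fold (SE 0.32). Muscle share was lower than in control in all 3 groups, as given above. Muscle levels of the control animals lay above those of every injected animal, so the muscle covariate can hardly be parted from group here. No fibroblast gene passed in edgeR with a batch term, where the list medians were -1.31, -1.47 and -1.01 in log2 in this order, or with the muscle covariate, where they were -2.03, -2.37 and -1.67.

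Of the followed matrix genes, FN1, HAS2 and POSTN fell against control with all 3 materials. FN1 fell 6.26-fold with Col1, 4.4-fold with VFLP_man and 3.75-fold with VFLP_au, and HAS2 3.8-fold, 3.72-fold and 2.93-fold in the same order. COL3A1, ELN and LOX fell with Col1 (3.22-fold, 2.72-fold and 2.64-fold) and with VFLP_man (2.37-fold, 2.1-fold and 2.51-fold), COL1A1 fell 3-fold with Col1, and ACTA2 fell 3.06-fold and MMP1 rose 7.5-fold with VFLP_man. With the muscle covariate the log2 fold changes of ACTA2 and MMP1 with VFLP_man turned to 1.48 and -0.37, and that of ELN with VFLP_man came to 0 in limma voom with that covariate, none of them past the test. Whether the materials differ in these genes was tested directly above, where none passed. The largest decreases included the muscle genes MYH13 (58.5-fold with Col1, 1270-fold with VFLP_man, 81.1-fold with VFLP_au), MYH4 (170-fold with Col1), MYH6 (2050-fold) and MYL3 (528-fold) with VFLP_man, GABRE (66.2-fold with Col1) and TCF15 (34.2-fold with VFLP_au). MYBPHL fell 64.4-fold with VFLP_au and had 1 read against 3726 with VFLP_man (95% counting interval of the ratio 1190 to 261000), ATP1A4 had 2 reads against 325 with Col1 (61 to 1840), and CA4 fell 61.6-fold with VFLP_au and had 0 reads with VFLP_man, at least 373-fold lower. A batch term turned the log2 fold changes of CA4 and TCF15 with VFLP_au to 1.31 and 2.5, and the muscle covariate turned that of MYH4 with Col1 to 0.01, none of them past the test. CRHBP rose from 0 control reads, at least 210-fold with VFLP_man and at least 83.1-fold with VFLP_au, and ANKRD1 rose 117-fold and 34.6-fold. IL2RA, a T cell activation receptor, rose 7.41-fold with Col1 and 13.6-fold with VFLP_au. CRISP2, FBP1 and TTC6 rose between 7.29-fold and 10.7-fold with Col1, PPEF2, OCM and DNAH17 between 29.9-fold and 59.2-fold with VFLP_man, and MKX 9.31-fold with VFLP_au. The entry ADORA1_1, a second row with the symbol of an adenosine receptor, rose 58.8-fold with Col1 and 39.8-fold with VFLP_au; its level ran from 3.27 to 39 CPM in the 10 libraries with reads on most mitochondrial rows, all 6 control libraries among them, and from 592 to 2420 CPM in the other 20.

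Against control 5702 genes passed in edgeR with Col1 (2396 higher, 3306 lower), 6623 with VFLP_man (2972 and 3651) and 4884 with VFLP_au (1918 and 2966), and 5046 differed among the 5 groups. A batch term gave 0, 29 and 0 genes for the materials in this order, and the muscle covariate gave 0 for them and for the 5 groups in edgeR (2695, 2375 and 2177 at an unadjusted p under 0.05 for the materials), where limma voom with that covariate gave 1180, 118, 577 and 730. Leaving out control animal 2 gave 3658 genes for Col1, 2528 for VFLP_au and 2924 for the 5 groups, leaving out VFLP_au animal 2 gave 3040 for VFLP_au, and left folds alone gave 18, 2867 and 1706 for the materials in the order above. Muscle list means of log2 CPM were at least 9.052 in control and at most 7.216 in the injected animals. The muscle covariate can therefore hardly be parted from group in these comparisons. The median of all genes was shifted by 0.12, 0.13 and 0.11 in log2.

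**Figure D3:**
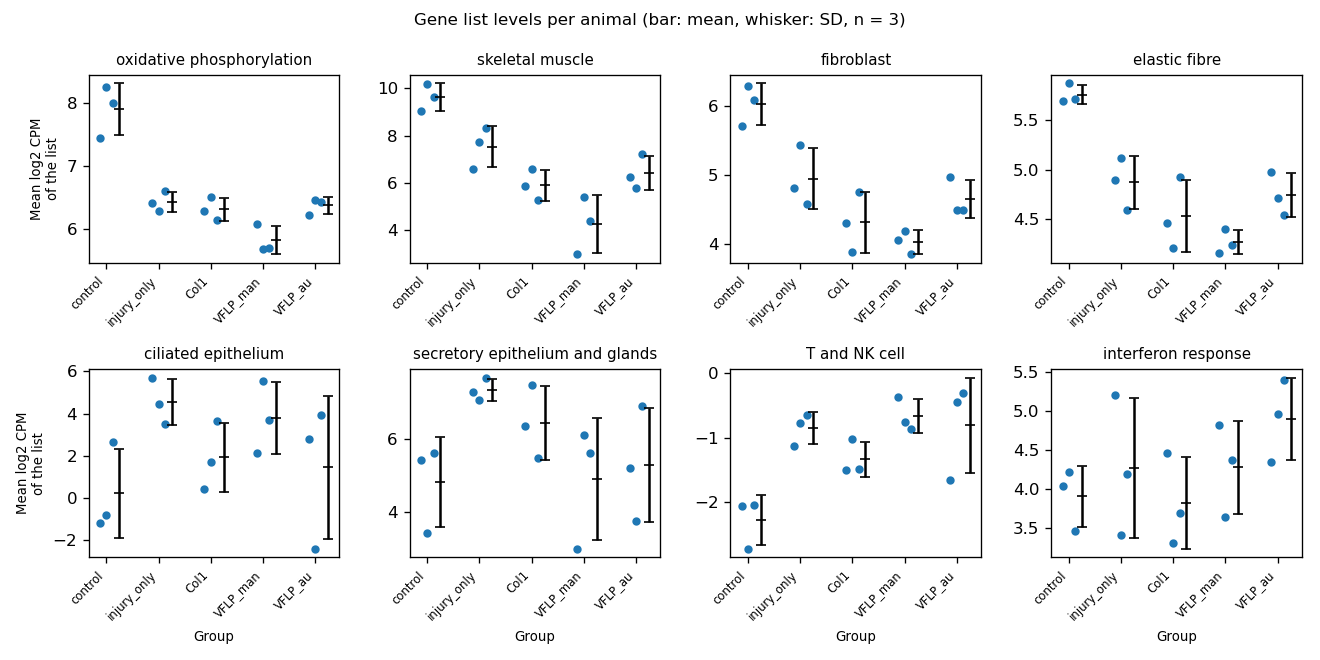
Mean log2 CPM of 8 gene lists in each animal (points) with the group mean and SD (n = 3 animals per group). Skeletal muscle means run from 9.62 in control to 4.25 in VFLP_man.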

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

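All 4 values below were singled out after the data were seen, by a fixed rule that sets the gap between a library and the nearest of the other 5 of its group against the range of the group. It was applied to 18 measures in 5 groups, 90 sets of 6 libraries, and chance picks out about 1 in 20 sets of independent values. The 4 values are about as many as that rate gives, and the 6 libraries are pairs of folds, which are not independent. No biological or technical explanation was tested for these values. The share of reads on ciliated epithelium genes was higher in the right fold of control animal 3, at a log2 percent of -4.75 against -10.14 to -8.27 in the other 5 control libraries. COL1A1 and TGFB1 both stood apart in the left fold of injury_only animal 2, at log2 CPM of 7.92 for COL1A1 (6.37 to 6.86 in the others) and 3.97 for TGFB1 (2.98 to 3.29 in the others). ACTA2 was at a log2 CPM of 6.02 in the right fold of VFLP_man animal 3, against 3.45 to 4 in the other 5 libraries of that group.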

How the results depend on the processing

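The muscle covariate in either tool, batch C injury libraries only, the low-depth library left out and mitochondrial rows left out were alternatives chosen only after the results were seen. The text names 279 gene results, 140 of them past the test. DESeq2 kept 139 of the 140 calls and its size factors in edgeR kept 134, the unstranded column 139, no filter 128 and the replicate block 112. Of the calls each could be tried on, limma voom on libraries kept 80 of 138, left folds 45 of 138, right folds 84 of 138 and the fit of only the 2 groups 92 of 137. Leaving out an animal lost 293 of 837 calls counted over all fits, and DESeq2 passed 50 of the 139 results that were not called. A batch term kept 0 of the 80 calls it could be tried on and the muscle covariate 20 of 140. That batch term raised the median SE over all genes from 0.31 to 0.44 for materials against injury_only and to 0.54 against control. A call lost with it therefore does not by itself show that the change was gone. Of 23 named gene list results, all called by camera, 2 were kept with an estimated correlation and 13 with fry. Counts stayed within 1.5 times under the settings not given below. The cause of a change was not tested. Fits of fewer groups or fewer animals have fewer samples, while single folds keep the same animals with fewer libraries each. Depth was not varied, so its part in what could be called was not tested. Folds of the same animal differed beyond counting error (chi-square per degree of freedom at least 56.2), and with simulated changes at these library sizes edgeR recovered 19% of 2-fold and 71% of 4-fold changes for injury_only against control.

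DESeq2 counts that moved were 380 genes for Col1 against injury_only, 1249 for VFLP_man against injury_only, 201 for VFLP_au against injury_only, 389 for VFLP_man against Col1, 35 for VFLP_au against Col1, 387 for VFLP_man against VFLP_au, 437 for the 3 injected materials and 7826 for the 5 groups. Limma voom on libraries, with animal as a random effect, gave 3 genes for Col1 against injury_only and VFLP_au against injury_only, 11 for VFLP_man against injury_only and VFLP_au against Col1, 5 for VFLP_man against Col1, 29 for VFLP_man against VFLP_au and 42 for the 3 injected materials. Libraries taken as separate samples, which counts each animal more than once, gave 6068 genes for injury_only against control, 382 for Col1 against injury_only, 1112 for VFLP_man against injury_only, 232 for VFLP_au against injury_only, 335 for VFLP_man against Col1, 25 for VFLP_au against Col1, 78 for VFLP_man against VFLP_au, 7503 for VFLP_au against control, 249 for the 3 injected materials and 9609 for the 5 groups. On those libraries, log2 fold changes turned to -0.02 for TGFB1 (VFLP_au against injury_only). HAS2 and LOX turned to -0.11 and -0.02 for VFLP_man against Col1. A fit of only the 2 groups compared gave 2136 genes for injury_only against control, 3 for Col1 against injury_only, 4 for VFLP_man against injury_only, 1 for VFLP_au against injury_only and VFLP_au against Col1, 2 for VFLP_man against Col1, 0 for VFLP_man against VFLP_au, 3628 for Col1 against control, 4094 for VFLP_man against control and 2670 for VFLP_au against control. With the unstranded column, log2 fold changes turned to -0.03 for HAS2 (VFLP_man against Col1). The fit of only the 2 groups was not run for the 2 tests across several groups.

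Left folds only gave 0 genes for injury_only against control and VFLP_man against VFLP_au, 711 for VFLP_man against injury_only, 327 for VFLP_man against Col1, 18 for Col1 against control, 2867 for VFLP_man against control, 1706 for VFLP_au against control, 121 for the 3 injected materials and 1663 for the 5 groups. In left folds, log2 fold changes turned to 0.33 and 0.02 for COL1A1 and ELN (injury_only against control). PVALB, ACTA2 and TGFB1 went to 0.45, -0.09 and -0.04 for Col1 against injury_only. POSTN came to -0.04 for VFLP_man against injury_only. ELN and TGFB1 came to -0.22 and -0.09 for VFLP_au against injury_only. COL1A1, COL3A1, ELN, HAS2 and LOX turned to -0.82, -0.01, -0.36, -0.92 and -0.62 for VFLP_man against Col1. COL1A1, FN1 and HAS2 turned to -0.42, -0.11 and -1.16 for VFLP_au against Col1. FN1 and HAS2 went to 0.18 and 0.23 for VFLP_man against VFLP_au. MMP1 came to -0.3 for VFLP_au against control. Right folds only gave 0 genes for VFLP_man against injury_only and VFLP_man against VFLP_au. In right folds, log2 fold changes turned to 0.29 and 0.24 for HAS2 and TGFB1 (VFLP_man against injury_only). COL3A1 and HAS2 came to 0.13 and 1.08 for VFLP_au against injury_only. TGFB1 turned to 0.12 for VFLP_man against VFLP_au.

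The replicate numbers join different animals, and profiles with the same number were no more alike within 30 pairs (mean correlation -0.01) than those with different numbers (0.01). The replicate block gave 1 gene for VFLP_man against Col1 and the 3 injected materials and 4 for VFLP_man against VFLP_au. With that block, log2 fold changes turned to 0.03 for MMP1 (Col1 against injury_only). HAS2 came to -0.04 for VFLP_man against Col1.

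A batch term in edgeR gave 0 genes for VFLP_man against injury_only, Col1 against control and VFLP_au against control and 29 for VFLP_man against control. With that term in edgeR, log2 fold changes turned to 0.61 and 0.26 for MYH3 and HAS2 (Col1 against injury_only). HAS2 and TGFB1 came to 0.29 and 0.26 for VFLP_man against injury_only. HAS2 turned to 0.64 for VFLP_au against injury_only. TGFB1 went to 0.26 for Col1 against control. TGFB1 came to 0 for VFLP_man against control. MMP1, TGFB1, CA4 and TCF15 went to -0.54, 0.1, 1.31 and 2.5 for VFLP_au against control. The skeletal muscle list for Col1 against injury_only turned upward there (camera adjusted p = 1.1e-08). Limma voom with a batch term gave 0 genes for VFLP_man against injury_only, Col1 against control, VFLP_man against control and VFLP_au against control. In that fit, log2 fold changes turned to -0.01 for ACTA2 (Col1 against injury_only). TGFB1 turned to 0.11 for VFLP_man against injury_only. HAS2 came to 0.17 for VFLP_au against injury_only. TGFB1 came to 0.11 for Col1 against control. With batch C injury libraries only there were 463 genes for VFLP_man against injury_only. With those libraries, log2 fold changes turned to -0.02 for ELN (VFLP_au against injury_only).

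The muscle covariate in edgeR gave 976 genes for injury_only against control and 0 for VFLP_man against injury_only, VFLP_man against VFLP_au, Col1 against control, VFLP_man against control, VFLP_au against control and the 5 groups. In each of these pairs of groups muscle levels did not overlap, so a lost call does not part muscle from group. With that covariate in edgeR, log2 fold changes turned to 0.8 for PVALB (Col1 against injury_only). HAS2, MMP1 and POSTN turned to 0.36, -0.83 and -0.64 for VFLP_man against injury_only. ELN, HAS2 and TGFB1 turned to -0.16, 0.04 and -0.01 for VFLP_au against injury_only. COL1A1, COL3A1, FN1 and LOX came to -0.73, -0.44, -0.06 and -0.33 for VFLP_man against Col1. ACTA2, HAS2 and POSTN came to 0.85, 0.25 and -0.19 for VFLP_man against VFLP_au. MMP1 and MYH4 came to -0.73 and 0.01 for Col1 against control. ACTA2 and MMP1 came to 1.48 and -0.37 for VFLP_man against control. ACTA2 and MMP1 turned to 0.81 and -1.55 for VFLP_au against control. The skeletal muscle list, on which the covariate is built, had an upward median for Col1 against injury_only (camera adjusted p = 0.33) and VFLP_man against injury_only (camera adjusted p = 0.68). Limma voom with the muscle covariate gave 1736 genes for injury_only against control, 1 for Col1 against injury_only, 0 for VFLP_man against injury_only, 4 for VFLP_au against injury_only, 8 for VFLP_man against Col1, 11 for VFLP_au against Col1, 20 for VFLP_man against VFLP_au, 1180 for Col1 against control, 118 for VFLP_man against control, 577 for VFLP_au against control, 31 for the 3 injected materials and 730 for the 5 groups. In the voom fit with that covariate, log2 fold changes turned to 0.36 and 0.3 for ELN and HAS2 (VFLP_man against injury_only). HAS2 went to 0.36 for VFLP_man against VFLP_au. ELN went to 0 for VFLP_man against control. ELN came to 0.09 for VFLP_au against control.

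Leaving out each animal in turn gave 1733 to 4286 genes for injury_only against control, 0 to 300 genes for VFLP_man against injury_only, 0 to 1 gene for VFLP_au against injury_only, 0 to 4 genes for VFLP_man against Col1, 0 to 1 gene for VFLP_au against Col1, 0 to 139 genes for VFLP_man against VFLP_au, 3658 to 6221 genes for Col1 against control, 4438 to 6762 genes for VFLP_man against control, 2528 to 5549 genes for VFLP_au against control, 0 to 28 genes for the 3 injected materials and 2924 to 5191 genes for the 5 groups. Log2 fold changes that turned sign without a single animal ran from -0.79 to 0.63 for ACTA2, -0.66 to 0.53 for MMP1 and -0.01 to 0.43 for TGFB1 (Col1 against injury_only). POSTN ran from -0.11 to 0.29 and TGFB1 ran from -0.21 to 0.17 for VFLP_man against injury_only. COL3A1 ran from -0.73 to 0, ELN ran from -0.25 to 0.37, HAS2 ran from -0.62 to 0.04, LOX ran from -0.57 to 0.14 and TGFB1 ran from -0.17 to 0.27 for VFLP_au against injury_only. COL1A1 ran from -0.42 to 0.6, HAS2 ran from -0.41 to 0.37 and LOX ran from -0.23 to 0.56 for VFLP_man against Col1. COL1A1 ran from -0.11 to 0.83 and TGFB1 ran from -0.4 to 0.05 for VFLP_au against Col1. COL1A1 ran from -0.94 to 0.44, COL3A1 ran from -0.68 to 0.12, FN1 ran from -0.64 to 0.06 and TGFB1 ran from -0.24 to 0.08 for VFLP_man against VFLP_au. TGFB1 ran from -0.27 to 0.17 for Col1 against control. MMP1 ran from -0.1 to 2.17 for VFLP_au against control. Without VFLP_au animal 3 there was 1 gene for VFLP_au against injury_only and for VFLP_au against Col1. Without VFLP_man animal 2 there were 4 genes for VFLP_man against Col1 and 28 across the 3 materials.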

Other observations

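The gene groups in the next paragraph, the test without the low-depth control library and the tests on mitochondrial genes were chosen only after the result was seen. The splits, the slopes on muscle share and the ratio between batches were planned.

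Endothelial genes were lower than in control in every group, in comparisons that share the same control animals. Of 21 measured members 4 fell in injury_only, 12 with Col1, 16 with VFLP_au and 17 with VFLP_man, or 3, 13, 17 and 17 adjusted over the list alone. Median log2 fold changes were -0.93, -1.48, -1.73 and -2.03 (camera adjusted p = 0.015, 0.00032, 1.1e-07 and 2.2e-06, and adjusted p = 0.72, 0.59, 0.31 and 0.35 with an estimated correlation). Fibrillar collagen genes, 9 in number, had a median log2 fold change of -0.6 in injury_only against control (camera adjusted p = 0.28). Against control 6 fell with Col1, 4 with VFLP_man and 3 with VFLP_au, the same numbers adjusted over the list alone, with medians of -1.69, -1.26 and -1.1 (camera adjusted p = 0.029, 0.054 and 0.015, and adjusted p = 0.52, 0.35 and 0.29 with an estimated correlation). Cartilage genes, which the cartilages next to the fold express, were lower in VFLP_man than in injury_only, with 1 of 15 past the test, 3 adjusted over the list alone and a median of -1.75 (camera adjusted p = 1.7e-05, and adjusted p = 0.087 with an estimated correlation). Interferon response genes were higher in VFLP_au than in control, with 3 of 15 past the test, 3 adjusted over the list alone and a median of 1.13 (camera adjusted p = 0.002, and adjusted p = 0.47 with an estimated correlation). With the muscle covariate the endothelial medians against control were -0.66 in injury_only, -0.69 with Col1, -1.02 with VFLP_au and -1.23 with VFLP_man, and no single endothelial gene passed in edgeR. No endothelial, fibrillar collagen, cartilage or interferon response gene passed in edgeR in the comparisons of injected folds above with either that covariate or a batch term, and injected folds and control lie in different batches. The interferon response median for VFLP_au against control was 0.09 with the covariate and 0.04 with the batch term. Control did not overlap the other groups in muscle level, so the covariate can hardly be parted from group there.

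Nuclear oxidative phosphorylation genes were lower in injury_only than in control, as was the muscle share. Without the control library of lowest depth 29 genes of the list still fell, which argues against 1 control library of low depth as the cause. The amount of skeletal muscle in the dissected piece cannot be told apart from an effect of injury: the slope on muscle share between the folds of 9 injected animals gave a median of 41.3% of the difference (jackknife SE 6.37). That slope was carried well beyond the data, since folds differed by -1.34 to 2.2 points of muscle share and the groups by -4.09. A change in the tissue after injury stays open and could account for the remainder.

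The 176 genes lower in VFLP_man than in injury_only may follow the amount of skeletal muscle in the dissected piece. The slope between folds of 9 animals of the other groups gave a median of 155% of the difference (jackknife SE 18.8), which overshoots the whole. With any 1 animal left out it was 140 to 168%, so the slope misses the size of the difference. The rule set beforehand had no upper limit, so an overshoot could not count against muscle. Some of the 176 genes are on the muscle list that gives the share, so their slope was set in advance. With muscle as a covariate the median log2 fold change went from -2.9 to -0.87. Muscle list means of log2 CPM were 2.951 to 5.406 in VFLP_man and 6.595 to 8.321 in injury_only. These do not overlap, so that covariate can hardly be parted from the material. Library batch cannot be told apart from the material, because 1 animal alone has a fold in each batch. In that animal, whose batch D fold also held less muscle (0.21% of reads against 1.92% in the batch C fold), the genes had a median log2 ratio of -2 between folds, and 1 of the 14 other animals, Col1 animal 1, was at or below it (-2.13), while a batch term, which rests on that animal and so mixes batch with its muscle difference, moved the median to -0.51. A direct effect of the material stays open and was not tested.

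Mitochondrial genes fell into 2 kinds of animals: 8 of the 13 protein genes reached 1000 CPM in 5 animals (all 3 controls, injury_only animal 2 and VFLP_man animal 3), and 3 reached it in the other 10. Both batches held both kinds (2 of 2), and so did 2 groups, which argues against library batch and against injury or injected material as the sole cause. Kind still went largely with group, since all 3 controls were of the first kind and every Col1 and VFLP_au animal of the second. Comparisons with control can therefore carry this difference between animals. Mitochondrial sequence that differs between animals is a candidate explanation, since the folds were alike in 15 of 15 animals. Reads on no gene made up 8.58 to 15.03% in the 20 libraries of the second kind and 5.07 to 8.07% in the others, and of 31309 genes ranked, ADORA1_1 alone parted the kinds by a wide margin, its lowest level in the 20 libraries being 15 times its highest in the 10. The sequence itself was not analysed here, so this stays open, and total mitochondrial reads were not compared between groups.

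Other splits of the same animals were counted for each comparison. For every pair of groups there are 10 splits, too few for a share under 0.05. Real counts and the highest of the other splits were 3933 and 0 for injury_only against control, 0 and 0 for Col1 against injury_only, 189 and 3 for VFLP_man against injury_only, and 0 and 0 for VFLP_au against injury_only. Between materials they were 0 and 2 for VFLP_man against Col1, 0 and 0 for VFLP_au against Col1, and 9 and 1 for VFLP_man against VFLP_au. Against control they were 5702 and 0 for Col1, 6623 and 1 for VFLP_man, and 4884 and 3 for VFLP_au. In the 4 comparisons with a real count of 0 all 10 splits gave as many, as they must, and in the others 1 did. For the 3 materials the real count was 0, which every split must reach, so that 100 of 100 splits drawn gave as many says nothing, and the highest other gave 89. For the 5 groups only the real split, 1 of 100, gave as many as 5046 genes, and the highest other gave 3472. That argues against chance in how the animals were divided, but not against batch or muscle share, which differ between the groups.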
